A study of Mus musculus with 6 samples.

How the data were processed

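Total RNA was sequenced from lymphocytes of 6-week-old C57BL/6 mice that had been sorted as CD19+ B220+ cells lacking surface IgM and IgD, with 3 libraries from thymus and 3 from Peyer's patches, the lymphoid follicles of the small intestine. Per the labels' protocols the thymus was digested with collagenase D and the Peyer's patches were not, so tissue and digestion coincide in every library. Libraries were made from total RNA with a stranded low-input kit. The labels do not say whether each library came from its own animal or from a pool, so the p-values measure only the spread between these samples, which may be technical.

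The deposited count table holds raw counts per gene, not normalised. Per the file headers the counts were made with featureCounts 1.6.2 on the mouse GENCODE release M22, in paired mode, with a mapping quality of at least 10 and strand setting 2, which is reverse-stranded counting. Per the submitters' processing notes the tools also included FastQC, Trimmomatic, HISAT2, SAMtools, Subread and edgeR, and the build was mm10. The authors also deposited a table of log2 CPM values for 15652 of the 55487 genes, on a log2 scale with a shared floor; how it was filtered is not given in the sources used here. Gene identifiers were matched without their version to symbols, and 55394 of 55487 had one; the 93 without a symbol held 0.0011% of all counts. There were 0 columns of per-sample values left unused. Multimapping reads fall under the mapping quality minimum, so genes with near-identical copies (Ly6c2, the Slfn, Ifit, Oas and Tgtp families, the H2-Q genes, Ighg2b with Ighg2c, Iglc2 with Iglc3, Hspa1a with Hspa1b) have uncertain levels.

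Library totals lay between 10284282 and 13639952 counts. From 27.9% to 32.9% of each total fell on Gm23935, Gm42418 and Gm26917, which carry ribosomal RNA-like sequence, and the rest on other genes. The 37 mitochondrial genes held 0 counts in every library. Replicates were not duplicates of one another: a chi-square statistic over genes was 19.4 to 31.8 times its degrees of freedom for every pair within a group.

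Counts were tested with edgeR 4.0.16 in R 4.3.3: filterByExpr with its defaults, TMM normalisation, glmQLFit with robust estimation and glmQLFTest on tissue alone over all 6 libraries, with Benjamini-Hochberg adjustment and a threshold of 0.05. A positive log2 fold change is higher in thymus. The standard error of a log2 fold change was taken as its size divided by the square root of the F statistic. CPM are TMM-scaled counts relative to library size, given as mean ± SD over 3 libraries. A fold against a group with no counts is a lower bound against a floor of 3 counts over the group; with 1 to 3 counts it is a ratio with an exact 95% interval. Floors and intervals cover counting error only, since reads without molecular identifiers are not independent molecules. On simulated counts for this comparison, drawn for 12979 genes with 200 changed, edgeR recovered 49% of genes changed by a log2 fold change of 1 and 84% of those changed by 2, and 6 of its 139 calls were false. The real comparison called 3446 genes, and the adjusted threshold depends on how many genes change. These rates therefore do not give its sensitivity.

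Gene sets were 29 lists fixed before the data were examined, as were the tests, the rule for named genes and the alternatives unless stated otherwise. Lists with at least 5 tested members were tested two-sided with camera from limma 3.58.1 at a preset inter-gene correlation of 0.01, adjusted over 23 lists, and again with an estimated correlation and with fry. Fry asks whether the genes of a list move, on balance, one way, and does not compare them with other genes. For each list the members past the threshold over all genes tested are counted, and those passing when adjusted over the list alone. Genes shared by lists count in each. Named genes were the 12 with the highest and the 12 with the lowest log2 fold change among those past the threshold with non-overlapping groups and a mean CPM of at least 10, leaving out immunoglobulin and T cell receptor segments and genes with only a clone name; from each list up to 4 members with the smallest p, or 2 with the highest CPM where none passed; and a fixed set of interferon, antigen presentation and B cell genes.

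Each library's share of counts on 8 heavy-chain constant genes, the Shannon entropy of its Ighv counts thinned to the smallest library's Ighv total, and the summed CPM of lists of other cell types were compared by exact two-sided permutation tests (scipy 1.17.1). With 20 assignments of 3 against 3 libraries the smallest p such a test can give is 0.1. Alternatives were other normalisations and filters, DESeq2 1.42.0, limma-voom, edgeR's glmTreat, leaving out immunoglobulin genes or ribosomal RNA, thinning, the replicate number as a block, limma on the deposited log2 CPM table, and leaving out each library in turn.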

Results

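Gene expression was measured in B cells sorted for CD19 and B220 and against surface IgM and IgD, from thymus and from Peyer's patch of 6-week-old mice, with 3 libraries each. The series asks how thymic B cells are activated and names type III interferon, so the comparison shows how these cells differ from B cells of a gut lymphoid tissue in which germinal centers form. Peyer's patch replicates 1, 2 and 3 held 12940578, 12541950 and 10562620 counts, and thymus replicates 1, 2 and 3 held 10284282, 10389279 and 13639952. Log2 CPM correlated across genes at r = 0.916 to 0.940 within a group and 0.804 to 0.824 between groups. The first principal component held 85.4% of the variance of the 500 most variable genes and parted the tissues. Malat1, a nuclear long non-coding RNA, took 0.890% to 1.04% of counts in Peyer's patch and 2.26% to 2.58% in thymus.

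Thymic and Peyer's patch B cells differed in many genes. Of 12979 genes tested, 1610 were higher and 1836 lower in thymus by edgeR's quasi-likelihood test, 1003 and 1027 of them by a log2 fold change of at least 1. Germinal center and cell cycle genes were lower in thymus, and interferon-stimulated genes, MHC class I genes and Aire were higher. The median log2 fold change of all tested genes was 0.014.

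The genes with the highest log2 fold change in thymus included several with no or almost no counts in Peyer's patch. Spon1, which encodes the secreted matrix protein F-spondin, had 37.0 ± 7.38 CPM in thymus (SD, n = 3) and no count in Peyer's patch, which made it at least 453-fold higher (adjusted p = 3.37e-10). Slfn1, a Schlafen family gene, was at least 352-fold higher. Ly6c2, which encodes the surface antigen Ly6C, had 78.5 ± 1.70 CPM in thymus and a single count in Peyer's patch, a ratio of 2846 with an exact 95% interval of 510 to 112500. The other 9 of the 12, in falling order of log2 fold change, were Rag1, Trabd2b, Ttn, Axl, Fcer1g, Ccl22, Lmna, Thsd7a and Rprm. The chemokine gene Ccl22 had a log2 fold change of 6.42 ± 0.22 SE. The log2 fold change of the receptor tyrosine kinase gene Axl (7.23 ± 0.42) was 8.73 without Peyer's patch replicate 1. The log2 fold change of the lamin gene Lmna (6.27 ± 0.64) was 7.85 without Peyer's patch replicate 3. All 9 Peyer's patch counts of the Fc receptor chain gene Fcer1g (6.62 ± 0.74) were in replicate 2. Trabd2b, Thsd7a and Rprm had 3, 21 and 25 counts in all of Peyer's patch, all or most of them in a single library. Ttn, which encodes the muscle protein titin, had 331 ± 33.6 CPM in thymus and 2.11 ± 1.80 in Peyer's patch. Rag1, the V(D)J recombinase gene, was at 33.0 ± 26.3 CPM in thymus. Its 3 thymus libraries were uneven, with 51, 389 and 762 counts, and with limma-voom its adjusted p was 0.0856.

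The 12 lowest genes by fitted log2 fold change were led by Rgs13, a regulator of chemokine receptor signalling in germinal center B cells (mm10 chromosome 1, 144138654 to 144177372). For a gene with no count in thymus only a bound on the fold is known, so its rank is uncertain. Rgs13 had 78.1 ± 8.65 CPM in Peyer's patch and no count in thymus, at least 882-fold lower (adjusted p = 1.86e-12). Tox2, Ephb2 and Emp2 also had no count in thymus and were at least 605-fold, 358-fold and 299-fold lower. Gcsam, a germinal center signalling adaptor (chromosome 16, 45610380 to 45622867), had 205 ± 23.2 CPM in Peyer's patch and 2 counts in all of thymus, a ratio of 3494 with an interval of 967 to 28850. Ackr4, Nuggc, Arhgap8, Rgs9, Cacna1h, Rsph1 and Eepd1 completed the group, with log2 fold changes from -9.32 for Ackr4 to -7.03 for Eepd1. Nuggc had 23 counts in thymus and the others 1 to 6, for each in a single library, so their folds rest on few counts.

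Genes of germinal center B cells were lower in thymus in 21 of 23 tested members, and the same number were lower when adjusted over the list alone. The median log2 fold change was -3.17. Cd86 was the member that was higher, and Kcnn4 did not pass. S1pr2, which confines cells to the follicle, fell by 5.79 on the log2 scale (SE 0.23), and the transcription factor gene Mybl1 fell by 4.68 (SE 0.17). Bcl6, the master regulator of the germinal center program, went from 299 ± 33.6 CPM in Peyer's patch to 44.6 ± 2.60 in thymus (adjusted p = 1.86e-12). The camera test gave an adjusted p of 2.65e-60, and 0.00492 with an estimated correlation.

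All 35 tested proliferation genes were lower in thymus, over all genes and when adjusted over the list alone. Mki67, the marker of cycling cells, was at 2566 ± 151 CPM in Peyer's patch and 156 ± 23.6 in thymus, a log2 fold change of -4.04 ± 0.11 SE (adjusted p = 6.17e-16). Top2a, Cenpf and Kif11, which act in chromosome segregation, had log2 fold changes of -3.39, -4.44 and -3.83. The list's median was -3.33, with an adjusted p of 3.58e-75 by camera and 0.00492 with an estimated correlation.

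Genes of class switching and somatic hypermutation were lower in thymus in 14 of 20 members, none was higher, and 14 were lower when adjusted over the list alone. Aicda, which encodes the deaminase that starts both processes, went from 131 ± 9.95 to 9.63 ± 2.69 CPM (log2 fold change -3.76 ± 0.20 SE, adjusted p = 2.06e-11). Polh, Msh6 and Parp1, which act in DNA repair and translesion synthesis, had log2 fold changes of -1.98, -1.44 and -0.84. Camera gave an adjusted p of 5.18e-07, which was 0.0663 with an estimated correlation. Aicda and Ung are also members of the germinal center list. Whether the list was lower apart from the lower proliferation genes was not tested.

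Interferon-stimulated genes were higher in thymus in 48 of 49 tested members, and in 49 of 49 when adjusted over the list alone. Their median log2 fold change was 2.72. Irf7, a transcription factor gene induced by interferon, rose from 9.49 ± 2.40 to 81.5 ± 15.4 CPM (log2 fold change 3.10 ± 0.24 SE, adjusted p = 3.16e-09), and Stat1, a transducer of interferon signals, from 55.2 ± 6.71 to 159 ± 11.1 CPM. Slfn8 (2.86 ± 0.18), Ifi203 (2.49 ± 0.17), Trim30a (2.15 ± 0.15) and Ly6e (1.27 ± 0.09) had the smallest p. Camera gave an adjusted p of 2.08e-40, and 0.012 with an estimated correlation. Among GTPases and chemokines associated with interferon-gamma, 16 of 16 tested members were higher, also when adjusted over the list alone, with a median of 1.95; Gbp7 (3.50 ± 0.30), Gbp5, Gbp9 and Igtp (3.06 ± 0.36) were examples. That list had an adjusted p of 7.09e-13, and 0.00936 with an estimated correlation.

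Of 9 tested genes for interferon receptors and transducers, 6 were higher and 1 lower in thymus, and the counts were equal when adjusted over the list alone. Ifnlr1, the specific chain of the type III interferon receptor (chromosome 4, 135686287 to 135708181), was at 5.04 ± 2.09 CPM in Peyer's patch and 30.9 ± 3.43 in thymus, a log2 fold change of 2.62 ± 0.37 SE (adjusted p = 1.10e-05). The second chain, Il10rb, had a log2 fold change of 1.17 ± 0.30 (adjusted p = 0.0061), which was 0.070 without thymus replicate 3. Ifngr2 (1.35 ± 0.17) and Ifngr1 (0.61 ± 0.15) were higher and the kinase gene Jak2 was lower (-0.56 ± 0.15). The type I receptor genes lay close to the threshold: Ifnar1 at 0.54 ± 0.19 (adjusted p = 0.0427) and Ifnar2 at 1.08 ± 0.39 (0.0451). Ifnar1 had an adjusted p of 0.184, 0.0896, 0.0672 and 0.195 without Peyer's patch replicate 1 or 3 or thymus replicate 1 or 2, and 0.0603 with library size only. Ifnar2 had 0.173, 0.188, 0.167 and 0.0959 without Peyer's patch replicate 1 or 2 or thymus replicate 1 or 2, and 0.0544 with library size only. Its log2 fold change was 1.70 without Peyer's patch replicate 3. The ligand genes Ifnl2, Ifnl3 and Ifnb1 had 0 counts in every library, and Ifng had 23 counts in thymus replicate 1 and 0 elsewhere. Camera gave an adjusted p of 0.0143 for this list, and 0.083 with an estimated correlation.

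**Figure D1:**
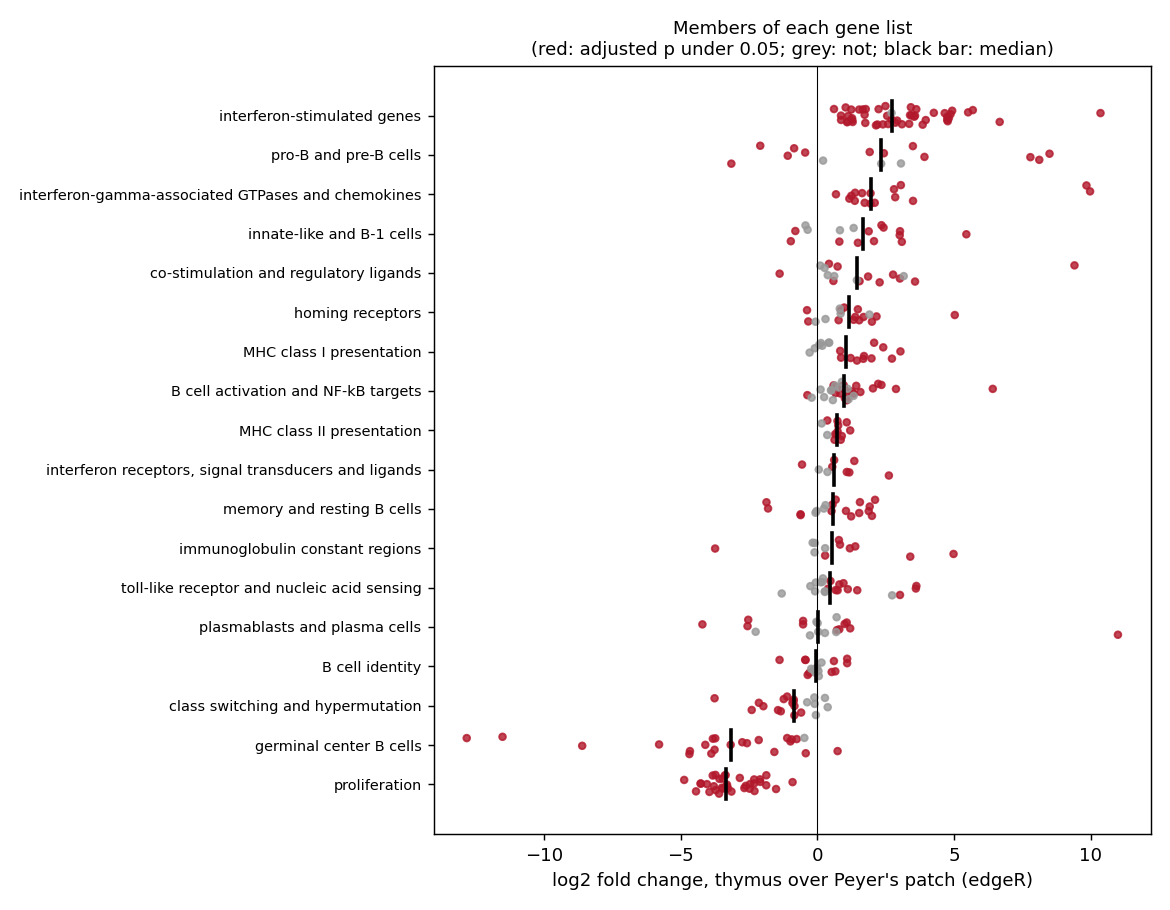
Log2 fold change (thymus over Peyer's patch, horizontal axis) of each tested member of the 18 gene lists on B cell biology with at least 5 tested members; each point is a gene, red where edgeR's adjusted p was under 0.05, and the black bar is the list's median. Interferon-stimulated genes had a median of 2.72, and the germinal center and proliferation lists had medians of -3.17 and -3.33.

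MHC class I genes were higher in 11 of 18 members and lower in none; adjusted over the list alone, 12 were higher and 1 lower. H2-K1, a classical class I heavy chain, rose from 373 ± 20.5 to 1573 ± 104 CPM (log2 fold change 2.08 ± 0.08 SE), its partner B2m by 1.98 ± 0.09, and Nlrc5, the class I transactivator gene, by 2.73 ± 0.15. H2-Q7 was also higher (3.04 ± 0.17). Camera gave an adjusted p of 3.1e-17, and 0.0178 with an estimated correlation. MHC class II genes rose less, in 11 of 13 members, also when adjusted over the list alone. H2-Ab1 had a log2 fold change of 0.76 ± 0.08, H2-Aa 0.86 ± 0.08, H2-Eb1 0.74 ± 0.07, the invariant chain gene Cd74 0.72 ± 0.07, the protease gene Ctss 1.20 ± 0.11 and the class II transactivator gene Ciita 0.74 ± 0.09. The class II list had an adjusted p of 1.68e-07 by camera, and 0.0946 with an estimated correlation. Whether the lists differed from each other was not tested.

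Co-stimulatory and regulatory ligand genes were higher in 10 of 17 members and lower in 1, also when adjusted over the list alone. Cd80, a ligand of CD28 and CTLA-4, rose from 4.59 ± 0.47 to 37.3 ± 4.54 CPM (log2 fold change 3.02 ± 0.31 SE, adjusted p = 1.49e-07), Pdcd1lg2 by 2.77 ± 0.31 and the lymphotoxin gene Ltb by 1.54 ± 0.14, whereas Slamf1 had -1.38 ± 0.20. Cd86 had 0.74 ± 0.21 (adjusted p = 0.0096, and 0.0833 without thymus replicate 1). Cd40 had 0.59 ± 0.17 (adjusted p = 0.0149, 0.0652 without Peyer's patch replicate 1 and 0.0817 without thymus replicate 1). The list's adjusted p was 0.000112, and 0.0284 with an estimated correlation. B cell activation genes and NF-kB targets were higher in 19 of 32 members and lower in 1, and in 22 and 1 when adjusted over the list alone. Ccl22 was at 150 ± 20.3 CPM in thymus and 1.74 ± 0.21 in Peyer's patch, and Fcrl5 (2.35 ± 0.16), the early activation marker gene Cd69 (2.04 ± 0.16) and Cd44 (1.33 ± 0.11) were also higher. Its adjusted p was 9.13e-13, and 0.00846 with an estimated correlation.

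Aire, which drives the expression of tissue-restricted antigens in the thymic medulla, was at 12.8 ± 7.22 CPM in thymus and 0.185 ± 0.256 in Peyer's patch, a log2 fold change of 5.99 ± 0.86 SE (adjusted p = 1.50e-05; chromosome 10, 78030022 to 78043610) that was 7.92 without Peyer's patch replicate 2. Aire was the member of its list that passed; of 17 self-antigen and related genes counted, 2 had enough counts to test, and Apoa1 had a log2 fold change of -2.13 without passing.

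**Figure D2:**
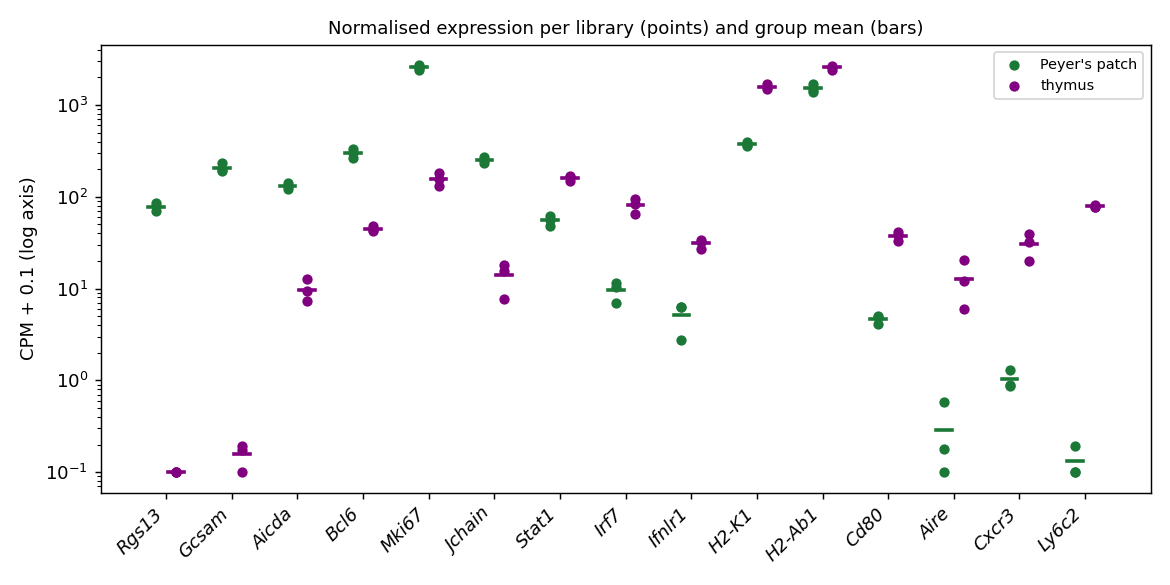
CPM plus 0.1 on a log axis for 15 named genes, with a point for each library (3 Peyer's patch in green, 3 thymus in purple) and a bar for the group mean. Mki67 averaged 2566 CPM in Peyer's patch and 156 in thymus, and Irf7 averaged 9.49 and 81.5.

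Genes of memory and resting B cells were higher in 11 of 19 members and lower in 4, also when adjusted over the list alone. The chemokine receptor gene Ccr6 (80.3 ± 18.5 CPM in Peyer's patch and 320 ± 16.9 in thymus), the quiescence factor gene Klf2 (log2 fold change 2.11 ± 0.18 SE) and Btg1 (1.05 ± 0.09) were higher, and Bach2, which restrains plasma cell differentiation, was lower (-1.80 ± 0.10). Klf2 and Btg1 are also members of the list of dissociation-induced genes, which was higher in the digested thymus. The memory and resting list had an adjusted p of 0.00218, and 0.0829 with an estimated correlation. Homing receptor genes were higher in 11 of 18 members and lower in 2 (14 and 2 when adjusted over the list alone), with Cxcr3 at 5.03 ± 0.44, Sell, which encodes L-selectin, at 1.53 ± 0.15, and an adjusted p of 4.09e-09, or 0.012 with an estimated correlation. Innate-like and B-1 cell genes were higher in 10 of 16 members and lower in 2 (11 and 2 when adjusted over the list alone), including Spn, which encodes CD43 (3.01 ± 0.17), Ptpn22 (3.09 ± 0.18) and Tlr7 (3.02 ± 0.24). That list had an adjusted p of 1.78e-07, and 0.0141 with an estimated correlation. Among toll-like receptor and nucleic acid sensing genes 11 of 21 were higher and none lower (12 when adjusted over the list alone), with Tlr9 at 0.81 ± 0.16, Unc93b1 at 0.67 ± 0.11 and Tmem173, which encodes STING, at 1.12 ± 0.20; the adjusted p was 0.00104, and 0.0663 with an estimated correlation.

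Plasmablast and plasma cell genes moved both ways, with 6 of 19 higher and 5 lower (8 and 5 when adjusted over the list alone), and the list did not pass (adjusted p = 0.163, and 0.29 with an estimated correlation). Jchain, which joins polymeric antibodies, fell by 4.21 on the log2 scale (SE 0.24) from 252 ± 21.1 CPM in Peyer's patch, and Prdm1, the plasma cell regulator gene, fell by 2.53 (SE 0.54), and had a log2 fold change of -2.19 without thymus replicate 1 and -3.23 without thymus replicate 3. Irf4 (1.07 ± 0.13) and the chaperone gene Hsp90b1 (0.80 ± 0.09) were higher. B cell identity genes were higher in 5 of 18 members and lower in 5 (5 and 6 when adjusted over the list alone). Their median was -0.036, whereas camera's direction was higher, without passing (adjusted p = 0.681, and 0.68 with an estimated correlation); the median was 0.046 with upper quartile scaling. Cd19 (0.61 ± 0.10), Cd79a (0.66 ± 0.09), Cd72 and Fcmr were higher, and Pou2af1 (-1.38 ± 0.10) and Ptprc (-0.30 ± 0.08) were lower. Ptprc had an adjusted p of 0.00996, which was 0.0685 without thymus replicate 1 and 0.0557 with upper quartile scaling.

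Pro-B and pre-B cell genes were higher in 7 of 15 members and lower in 5, also when adjusted over the list alone. Hmgn2 (-2.09 ± 0.14 SE), Vpreb3 (-3.15 ± 0.47), Smarca4, Cd24a and Ebf1 (-0.45) were lower. Rag1, Igll1, Sox4 and Lef1 were among the 7 higher. Igll1 had 0 counts in Peyer's patch and 106 in thymus, Sox4 47 and 521, and Lef1 42 and 226. Dntt had 0 and 134. The median was 2.34 while camera's direction was lower, without passing (adjusted p = 0.803, and 0.922 with an estimated correlation).

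Heavy-chain constant-region genes differed in make-up between the tissues. Ighg1 (chromosome 12, 113325240 to 113330523) took 14.4% ± 5.46 of the counts on 8 heavy-chain genes in Peyer's patch (SD, n = 3) and 0.968% ± 0.267 in thymus, and Ighg2c (chromosome 12, 113285325 to 113288932) took 0.327% ± 0.307 and 8.74% ± 1.64. Ighm took 25.9% ± 3.02 in Peyer's patch and 39.7% ± 4.56 in thymus although the sort excluded surface IgM. Each of these, and Ighg2b (33.4% ± 0.093 and 27.8% ± 1.66), Ighg3 (1.24% ± 0.386 and 2.54% ± 0.584) and Ighe (0.0498% ± 0.0446 and 0.479% ± 0.0639), had an exact permutation p of 0.1, the smallest this design allows. Igha took 19.3% ± 2.51 and 15.3% ± 1.98 (exact p = 0.2), and Ighd 5.45% ± 1.18 and 4.52% ± 0.266 (exact p = 0.4). The difference in Ighd was -1.55 points without Peyer's patch replicate 1 and -0.369 without Peyer's patch replicate 3. Without Ighd and Ighm in the sum, the difference between thymus and Peyer's patch turned from -5.60 to 1.16 points for Ighg2b and shrank from -4.03 to -0.929 for Igha. It grew from -13.4 to -18.9 for Ighg1, from 8.41 to 15.1 for Ighg2c, from 1.31 to 2.86 for Ighg3 and from 0.430 to 0.787 for Ighe.

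Over all genes, 7 of 12 immunoglobulin constant-region genes were higher in thymus and 1, Ighg1, was lower, also when adjusted over the list alone. Ighm had a log2 fold change of 0.79 ± 0.10 SE, Ighg3 1.19 ± 0.23, Iglc2 1.39 ± 0.16 and Iglc3 0.83 ± 0.12. Igha (-0.17 ± 0.11, adjusted p = 0.306) and Ighd (-0.09 ± 0.13, adjusted p = 0.672) did not pass. The list had an adjusted p of 0.0152, and 0.124 with an estimated correlation. These counts do not separate mature from germline transcripts.

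**Figure D3:**
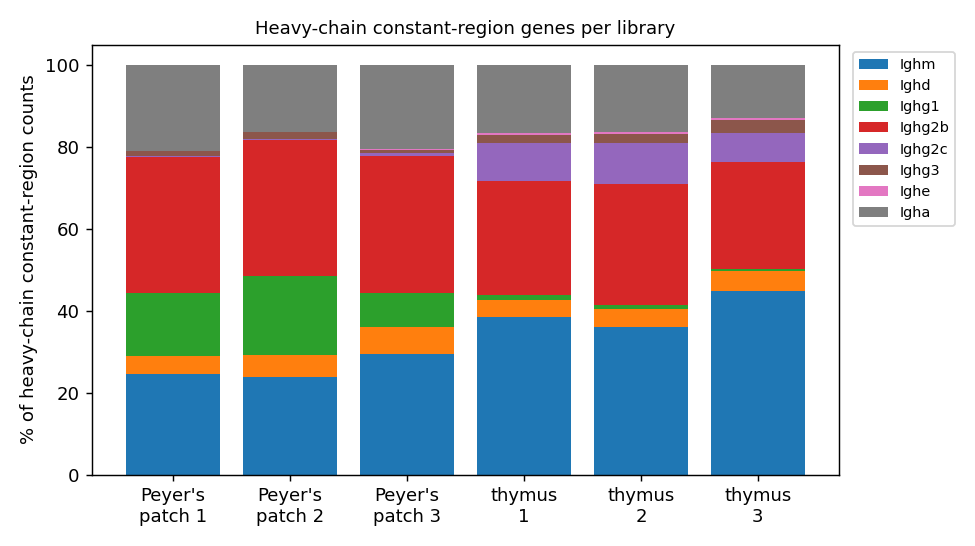
Stacked bars of the share (%) of heavy-chain constant-region counts on each of 8 genes, for 3 Peyer's patch and 3 thymus libraries. Ighg1 averaged 14.4% in Peyer's patch and 0.968% in thymus, and Ighg2c 0.327% and 8.74%.

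Heavy-chain V gene usage was broad in both tissues. The entropy of Ighv counts was 5.48 ± 0.164 bits in Peyer's patch and 5.68 ± 0.0375 bits in thymus (SD, n = 3, exact permutation p = 0.2). The difference of 0.209 bits was 0.134 without Peyer's patch replicate 1 and 0.296 without Peyer's patch replicate 2. The most used Ighv gene held 9.76% ± 0.901 of Ighv counts in Peyer's patch and 7.45% ± 0.715 in thymus (exact permutation p = 0.1, the smallest possible). With Igkv genes this difference pointed the other way, at 7.77% ± 1.80 and 10.2% ± 1.10 (exact p = 0.3). The libraries held 4789 to 6196 Ighv counts.

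Transcripts of other cell types were scarce but moved with tissue for some lists. The summed CPM of the T cell list was 221 ± 11.9 in Peyer's patch and 442 ± 10.7 in thymus (exact permutation p = 0.1). Of its 10 tested members 6 were higher and none lower; adjusted over the list alone, 6 were higher and 1, Lck, was lower. Cd2 (log2 fold change 1.95 ± 0.13 SE), Tcf7 (4.45 ± 0.47) and Cd5 (5.45 ± 0.76, and 7.77 without Peyer's patch replicate 3) were higher, and Zap70 was at least 49.3-fold higher. Cd5 is also expressed by B-1 cells and Cd2 by mouse B cells. Cd3e, which was below the test's filter, had 12, 12 and 0 counts in thymus and 0 in Peyer's patch. Cd3g, which was above it, had 50, 33 and 30 counts in thymus and 0, 4 and 0 in Peyer's patch. Camera gave the T cell list an adjusted p of 2e-04, and 0.0328 with an estimated correlation. Macrophage, monocyte and neutrophil genes summed to 40.8 ± 6.73 and 207 ± 23.2 CPM (exact p = 0.1), of which Mpeg1, also expressed in B cells, took 34.6 ± 7.05 and 180 ± 19.5. Vcam1 and Adgre1 were at least 147-fold and 85.0-fold higher in thymus. That list had 3 of 6 tested members higher, also over the list alone, with an adjusted p of 0.00379, and 0.0663 with an estimated correlation.

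Dendritic cell genes summed to 87.5 ± 18.4 CPM in Peyer's patch and 219 ± 25.7 in thymus (exact p = 0.1), with Sirpa (2.40 ± 0.30 SE), Fscn1 (1.42 ± 0.19) and Zbtb46 (3.54 ± 0.77, and 5.25 without Peyer's patch replicate 1) higher, 3 of 6 over all genes and when adjusted over the list alone. Their adjusted p was 0.00996, and 0.252 with an estimated correlation. Genes of thymic epithelium and stroma summed to 112 ± 12.7 and 205 ± 3.08 CPM (exact p = 0.1), most of it Pecam1, which was higher (1.10 ± 0.14). Of its 5 tested members 2 were higher, also over the list alone, the other being Kdr, at least 22.1-fold. Kdr had an adjusted p of 0.0106, and 0.055 and 0.0797 without Peyer's patch replicate 1 or thymus replicate 1. The list did not pass (adjusted p = 0.16, and 0.271 with an estimated correlation).

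Intestinal epithelial genes summed to 28.3 ± 35.2 and 6.86 ± 5.47 CPM (exact p = 0.4), with 68.9 CPM in Peyer's patch replicate 2, without which the difference shrank from -21.4 to -1.10. None of 4 tested members passed by edgeR; Epcam had 0.50 ± 0.86 SE and Lgals4 0.38 ± 1.37. Erythroid genes summed to 30.1 ± 3.63 and 27.4 ± 22.6 CPM (exact p = 0.8). The difference of -2.73 was -15.1 without thymus replicate 2 and turned to 7.06 without thymus replicate 3. Bpgm, 1 of 2 tested, was lower (-1.23 ± 0.34, adjusted p = 0.0093, and 0.055 without Peyer's patch replicate 2). Natural killer and innate lymphoid genes summed to 8.16 ± 3.12 and 10.2 ± 3.69 CPM (exact p = 0.5), a difference of 2.06 that was 0.414 without Peyer's patch replicate 1 and 4.12 without thymus replicate 3. Neither tested member passed, with Prf1 at 1.23 ± 0.63 and Tyrobp at -1.74 ± 0.93. Mitochondrially encoded genes had 0 counts. Xist was expressed in every library, and its log2 fold change of 0.25 ± 0.08 had an adjusted p of 0.0259, which was 0.12, 0.168 and 0.0565 without Peyer's patch replicate 1, thymus replicate 2 or thymus replicate 3, and 0.078 with library size only.

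Dissociation-induced immediate early genes were higher in thymus in 19 of 31 members and lower in 3, and in 20 and 3 when adjusted over the list alone. Jun rose from 58.0 ± 7.88 to 221 ± 12.1 CPM (log2 fold change 1.93 ± 0.13 SE), and Ier5 by 1.53 ± 0.12. The list had an adjusted p of 1.44e-08, and 0.0141 with an estimated correlation. Since the thymus alone was digested with collagenase, tissue and digestion cannot be told apart for any gene. The setting of camera is also a limit: 19 of 23 lists passed with the preset correlation and 11 with an estimated one. The size of the correlation alone does not account for this. For interferon receptors the estimate was -0.00314, below the preset 0.01, and camera's adjusted p still went from 0.0143 to 0.083. Among the other 9 splits of the libraries up to 17 lists passed with the preset correlation and 0 with an estimated one. Each of those splits mixes the tissues, so they do not measure how often a list passes by chance.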

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

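The test of the genes kept in the deposited table and the count of lists over other splits with an estimated correlation were chosen after seeing the data. The counts of genes higher and lower in thymus stayed within 1.5 times the main counts under other normalisations, filters, tests, thinning and the deposited log2 CPM values. The exception was edgeR's test against a log2 fold change of 1, with 522 genes higher and 614 lower, since it asks for a larger difference. Restricted to genes kept in the deposited table, 1263 were higher and 1521 lower. Without each library in turn, 1369 to 1515 genes were higher and 1514 to 1723 lower. Upper quartile scaling moved the median of all genes by 0.082 and the share of calls higher in thymus from 46.7% to 53.7%.

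The replicate numbers showed no sign of pairing: same-numbered libraries correlated at 0.015, -0.027 and -0.012 in their deviations from the group means. Libraries with different numbers lay between -0.02 and 0.031. A shared mouse need not leave such a correlation, so pairing is not excluded. With the replicate number as a block, 1542 genes were higher and 1782 lower, and no list changed its call; the pro-B and pre-B list, called by neither fit, turned its direction (adjusted p = 0.793).

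With an estimated correlation 11 of 23 lists passed. The lists that lost their call were interferon receptors (adjusted p = 0.083), MHC class II (0.0946), memory and resting B cells (0.0829), immunoglobulin constant regions (0.124), class switching (0.0663), toll-like receptors (0.0663), macrophages (0.0663) and dendritic cells (0.252). With fry, plasma cells (0.0129), B cell identity (0.0176) and thymic epithelium (0.01) passed too. Fry does not compare a list with other genes. The pro-B and pre-B list had adjusted p from 0.277 to 0.951 without each library, and pointed higher without thymus replicate 1.

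Without Ighd and Ighm in the sum, the difference in share between thymus and Peyer's patch was -18.9 points for Ighg1, 1.16 for Ighg2b, which reversed, 15.1 for Ighg2c, 2.86 for Ighg3, 0.787 for Ighe and -0.929 for Igha. Ighm took 25.9% of the full sum in Peyer's patch and 39.7% in thymus, so leaving it out raised the other shares more in thymus. The share of the most used V gene reversed to 2.42 points with Igkv; the cause was not tested. Of 124 named genes, 83 kept their call in every setting that tested them. The direction turned for Epcam (-0.42 without thymus replicate 1, up to 0.97 without the others), Lgals4 (-0.20 without Peyer's patch replicate 3, and from -0.47 without thymus replicate 1 to 0.70) and Ighd (from -0.22 to 0.0026, the latter without Peyer's patch replicate 3). None of these was called. The test against a log2 fold change of 1 ended 36 calls. Depth limits genes of a few counts, such as Cd3e.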

Other observations

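The tests of other cell types, of B cell state, of digestion, of Rag1 and of gene length were chosen after their values had been seen, as were the lists of metabolic and muscle genes.

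Genes of cholesterol synthesis and uptake were lower in thymus in 14 of 22 members (15 when adjusted over the list alone), including Ldlr (log2 fold change -5.11), Sqle (-4.87) and Fdps (-4.73). The list was made because Sqle and Ldlr stood out. Without them 12 of 20 members were lower. Camera gave a p of 2.3e-06 (adjusted 5.75e-06) at the preset correlation and 0.0817 (adjusted 0.136) with an estimated correlation. For the metabolic and muscle lists the adjustment was over the 5 lists added after the data were seen. Nuclear genes of oxidative phosphorylation were lower in 15 of 31 members (median -0.52), with an adjusted p of 0.085 with an estimated correlation. Cytosolic ribosomal protein genes had a median of 0.028, which was -0.0001 with library size only, and 5 of 37 higher and 3 lower.

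Ttn had 3022, 3952 and 4225 counts in thymus, where Acta1, Des and Myh1 had 1, 0 and 0 in all, Ckm had 13 and Tnnt3 had 65. Of 5 tested members of a muscle list made without Ttn, none was called higher and 2, Mylpf and Ryr1, were lower in thymus. The list's camera adjusted p was 0.217, and 0.371 with an estimated correlation.

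Other splits of the 6 libraries were compared on both counts, and each of them had both tissues on both sides. The real split gave 3446 genes and the highest of the others 0, and it gave 19 lists and the highest of the others 17. In each case 1 of 10 splits reached the real count, and 10 splits are too few for a share under 0.05. The splits that called up to 17 lists called no gene. Part of the tissue difference can remain in a mixed split, so these lists are not a count of false calls. A list passing only at the preset correlation is still weak evidence by itself. With an estimated correlation the real split gave 11 lists and the others 0. In the other splits the tissue difference adds to the spread within groups. Few calls there were built in, so they lend the real split no support.

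Interferon-stimulated genes were higher in thymus. The choice among 4 scalings did not account for this, since the lowest median over them was 2.71. These scalings moved the median of all genes by only -0.0261 to 0.082, so they could not have removed the difference. None of them measures RNA per cell, and a difference in it was not tested. For macrophages or monocytes as the source, the sum of C1qa, C1qb, C1qc, Lyz2 and Csf1r did not rise in thymus. These were chosen after their values were seen, and all but Lyz2 were below the test's filter. Their sum therefore does not exclude such cells. These 5 transcripts, of a list of 20, summed to 0.848 to 3.50 CPM in Peyer's patch and 0.466 to 3.13 in thymus. This was a change of -0.0056% of the rise of the interferon list, with a sign that depends on single libraries. Adgre1, Vcam1 and Mpeg1 were higher all the same, and Csf1r, which was below the test's filter, had 16 counts in Peyer's patch and 53 in thymus. Macrophages or monocytes therefore stay open. Dendritic or plasmacytoid cells, which a sort for CD19 selects against, stay open: the dendritic list rose by 3.45% of that rise, with Zbtb46, Sirpa and Fscn1 higher, Flt3 and Itgax not called, and Siglech at 8 counts in Peyer's patch and 11 in thymus. That the cells are in different states, with a germinal center median of -3.17, stays open because state, tissue and digestion coincide, and no sample tests exposure to interferon.

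Immediate early genes were higher in thymus. The lowest median over 4 scalings was 0.942, so the choice among them did not account for the rise. They moved the median of all genes by at most 0.082 and could not have removed it. A difference in RNA per cell was not tested. Collagenase digestion may have raised them, with a median of 0.968, but only thymus was digested, so digestion cannot be told apart from tissue.

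Rag1 was uneven among the thymus libraries. Thymocytes, which a sort for CD19 selects against, stay open because 8 of 9 T lineage transcripts were below the test's filter: their sum rose over Peyer's patch by 27.6% of the rise of Rag1, but its order among thymus replicates 1, 2 and 3 (12.4, 11.9 and 4.07 CPM) was not that of Rag1 (5.15, 36.3 and 57.5). Pro-B or pre-B cells in the sort are a candidate explanation: 7 of 14 other tested members of the precursor list ordered the thymus libraries as Rag1 did, against 18.02% of all tested genes (exact binomial p = 0.00645, with genes that are not independent). The test was chosen after the values were seen, so its p is not independent support. Of the 7, Igll1, Sox4 and Lef1 were higher in thymus, Smarca4 and Ebf1 were lower and Il7r and Myb were not called. The tested Dntt, with 39, 25 and 70 counts, and the untested Rag2, with 11, 3 and 7, did not follow the order. A sort against surface IgM would keep such cells, and a difference between the thymuses themselves was not tested.

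The deposited log2 CPM table may have been filtered on gene length compared as text. Of genes with at least 10 counts in every library, 100% of the 8303 whose length sorts at or after 200 as text were present and 0% of the 1948 whose length sorts before it. In all, 2617 of the genes tested here were missing there, 669 of them called, Mki67, Cd74, Ptprc and Ighm among these, while 311 genes shorter than 200 bases were kept.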
